A study of Sordaria macrospora with 14 samples.

How the data were processed

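The deposited table holds raw read counts per gene model for the 14 libraries, per the file headers, together with the length of each gene model and the authors' own comparisons. The counts are whole numbers whose totals differ between libraries. The aligner, the counting program, the genome build and the handling of strand and of reads with several matches are not given in the sources used here; counts of genes with close copies or overlapping neighbours are therefore uncertain. Libraries were sequenced on an Illumina instrument, per the labels. The extraction text of the labels also speaks of RNA from microdissection, while each sample is named as mycelium or perithecia; samples were taken as named, and whether any library came from dissected material is not given in the sources used here. DESeq2 was used, per the submitters' processing notes, which state no version. The authors' deposited table also gives a mean normalized signal over all libraries, the log2 fold change and the adjusted p-value of each of their comparisons, per the file headers; those p-values are written to 2 decimals. These columns were compared with the results here and entered no test. With DESeq2 1.42.0 on the deposited counts, log2 fold changes lay within 0.02 of the authors' values for 9799 to 9829 of 9853 genes in 6 comparisons.

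The table lists 10014 gene models. A further 145 rows for second transcripts hold no count in any library and were left out. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 7 groups, which left 9499 gene models; 515 were left out, 161 of them with no count in any library, and together they held 0.00468% of the counts. TMM scaling factors were used, dispersions were estimated over all 14 libraries (common biological coefficient of variation 0.237), and the quasi-likelihood test (glmQLFit and glmQLFTest) was run on 1 model with a mean for each group. The model has 7 residual degrees of freedom and 5.50 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are called higher or lower. Standard errors of log2 fold changes were computed from the fold change and its F statistic. Values per gene are CPM (counts-per-million) on scaled library sizes, with the mean and SD of 2 replicates. A gene with 0 counts in a group is given a bound against a floor of 3 counts over that group; bounds, and the 95% exact interval of a ratio of counts, cover counting error only.

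There were 11 comparisons: perithecia against mycelium in each of 3 strains, each deletion strain against the wild type in the same tissue, Δasm2 against ΔSMAC_03952 in perithecia, and the interaction of strain and tissue for Δasm2 and ΔSMAC_03952. The comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, genes past the threshold whose replicates did not overlap between the groups and whose higher group reached 10 CPM, ordered by fold change. For the interactions, which join 4 groups, the script took the threshold and the 10 CPM in any of the 4 and did not ask for replicates that do not overlap; this reading of the rule was not fixed in advance and was made once the counts were at hand. No table used here pairs the identifiers with names or products: of the gene models, 9531 matched a locus tag in the RefSeq annotation ASM3387043v1, which gave 0 symbols other than locus tags. The rule therefore names 2 genes that rose and 2 that fell per comparison for the 8 comparisons that involve the wild type, plus SMAC_03952 in 6 of them, the interactions left out. The genes behind the names asm2 and spt3 could not be looked up for the same reason. Gene lists for pathways and for markers of asci, pigmented perithecial wall, mating and stress had been planned through product names or protein motifs, and were not run because they need names or sequences that were not used here. Gene groups in the text are therefore sets of genes called in 1 comparison and followed in another, tested with camera in limma 3.58.1 on log2 CPM. The annotation is of another build than the counts may use, so it served only to find which genes neighbour each other, and no positions are given.

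The labels state that the replicates are independent biological ones. The replicates of every group differed by far more than sampling noise (chi-square per gene between 12.3 and 132), so no library was counted as a copy of another. The total count per library ranged from 6383079 to 24029990. The most abundant gene model, SMAC_12697, took 4.99% of the counts of wild-type mycelium replicate 1, and the 10 most abundant took at most 10.3% of any library. The method was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per comparison: between 80% and 94% of changes of 4-fold and between 11% and 26% of changes of 2-fold were recovered in the comparisons of 2 groups. For the interactions, 43% (Δasm2) and 33% (ΔSMAC_03952) of 4-fold changes were recovered and 4% and 1% of 2-fold changes. Few genes changed in these simulations, which makes the adjustment stricter than with the 171 and 1342 interaction genes called in the data. The shares therefore do not give the power in the data. The 50 higher and 121 lower Δasm2 interaction genes had medians of 1.94 and -2.05 on the log2 scale. Interactions below 4-fold were therefore also called.

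Comparisons that share the wild-type libraries were set against 20 simulations in which the mutant groups had the wild-type means, and against the overlap of independent lists of the same sizes. Alternatives fixed in advance were RLE scaling factors, no filter on low counts, DESeq2, a fit of only the libraries compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and each replicate left out in turn. Library totals without scaling factors, thinning of all libraries to the smallest total, offsets that remove each library's trend with gene length, and an exchange of replicate numbers were added after the data were seen, as were the test of the difference between both interactions and the analysis of neighbouring genes. Neighbouring genes were counted with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, against 1000 shuffles of the calls over the positions of 9173 protein-coding genes.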

Results

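RNA was sequenced from 4 strains of Sordaria macrospora, a self-fertile filamentous ascomycete. Its fruiting bodies, the perithecia, are flask-shaped structures in which asci and ascospores form. The strains were the wild type and the deletion strains Δasm2, ΔSMAC_03952 and Δspt3; spt3 shares its name with a subunit of the SAGA transcriptional coactivator complex of yeast. Sexually developing mycelium came from liquid culture, and perithecia were scraped from solid medium after a fixation in ethanol of 10 min. Both kinds of culture were grown for 6 days at 25 °C. The wild type, Δasm2 and ΔSMAC_03952 were sampled as mycelium and as perithecia, and Δspt3 as mycelium only, which gave 7 groups of 2 biological replicates, 14 libraries in all. The total count per library ranged from 6383079 in ΔSMAC_03952 perithecia replicate 1 to 24029990 in wild-type mycelium replicate 1. Between 8924 and 9193 gene models reached 1 CPM (counts-per-million) in the 12 libraries of the other groups, against 8358 and 8433 in the Δspt3 libraries. Across genes, Spearman's correlation between the replicates of a group lay between 0.955 and 0.992.

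On the first principal component, which held 55.4% of the variance of log2 CPM, the Δspt3 libraries lay at 158 and 170. Every other library lay between -52.0 and 9.44. The second component held 18.5% and ordered the remaining libraries by tissue: perithecia lay between 13.5 and 65.8 and mycelium between -55.9 and -14.2.

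**Figure D1:**
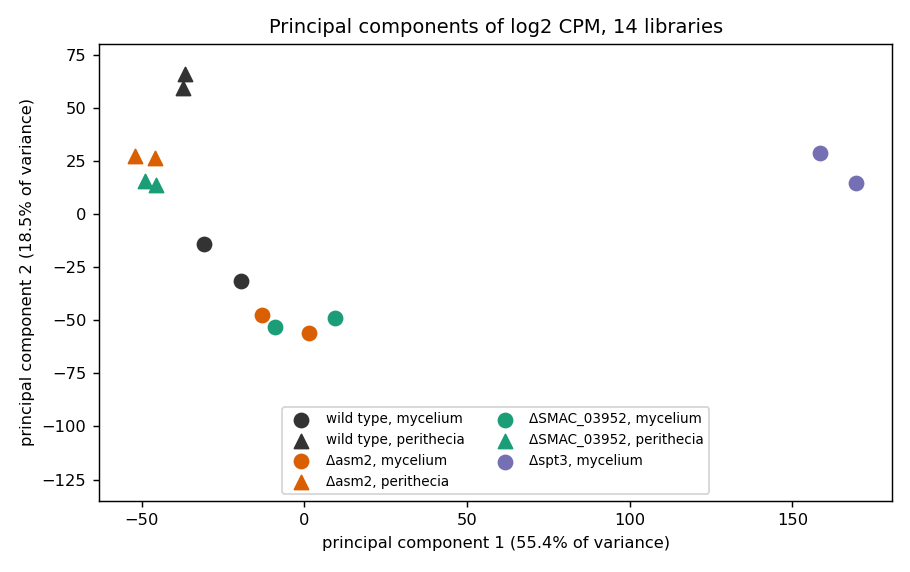
Each point is 1 library, placed by its first principal component (x axis, 55.4% of the variance of log2 CPM) and its second (y axis, 18.5%); circles are mycelium, triangles are perithecia and colours are strains. The 2 Δspt3 libraries lie at 158 and 170 on the x axis, away from the other 12, and the perithecia lie above the mycelium libraries of the same strain.

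The deleted gene was examined first in the only strain whose target carries its identifier in its name. SMAC_03952 stood at 238 ± 1.53 CPM (mean ± SD, n = 2) in wild-type mycelium and at 176 ± 6.25 CPM in wild-type perithecia. In the ΔSMAC_03952 strain it stood at 23.2 ± 2.71 CPM in mycelium and at 40.4 ± 7.45 CPM in perithecia. Relative to the wild type it fell by 3.36 on the log2 scale in mycelium (SE 0.24, edgeR adjusted p = 5.02e-05) and by 2.12 in perithecia (SE 0.23, edgeR adjusted p = 5.26e-05). Part of the signal remained, 9.73% of the wild-type level in mycelium and 23.0% in perithecia. The deletion libraries lay below all others of their tissue: the lowest value elsewhere was 108 CPM in mycelium, in a Δspt3 library, and 171 CPM in perithecia. In Δspt3 mycelium the gene stood at 126 ± 26.0 CPM and was lower than in the wild type by a log2 fold change of -0.92 (SE 0.22, edgeR adjusted p = 0.00316; -0.59 with length trends removed, edgeR adjusted p = 0.032). It did not differ from the wild type past the threshold in Δasm2 mycelium (log2 fold change 0.07, edgeR adjusted p = 0.883) or Δasm2 perithecia (0.51, edgeR adjusted p = 0.151).

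**Figure D2:**
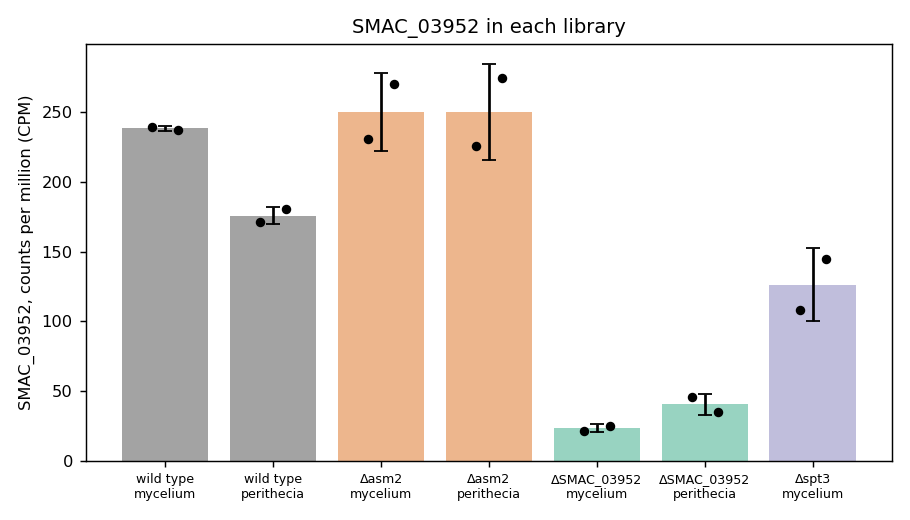
Bars give the mean CPM of SMAC_03952 in each of the 7 groups, error bars the SD of 2 replicates, and black points the single libraries; the y axis is linear and starts at 0. The ΔSMAC_03952 groups stand at 23.2 and 40.4 CPM, below every other group.

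The wild-type perithecia were compared with wild-type mycelium to ask which genes change with the formation of the fruiting body. Of 9499 genes tested, 2662 differed, 1401 of them higher in perithecia and 1261 lower. SMAC_03548 rose from 0.810 ± 0.113 CPM in mycelium to 22.5 ± 2.57 CPM in perithecia, a log2 fold change of 4.78 (SE 0.55, edgeR adjusted p = 1.07e-04). SMAC_05680 rose from 33.0 ± 13.5 to 775 ± 113 CPM (log2 fold change 4.55, SE 0.44, edgeR adjusted p = 2.54e-05). In the other direction, SMAC_08704 fell from 380 ± 163 to 2.91 ± 0.315 CPM, 131-fold (SE 0.37 on the log2 scale, edgeR adjusted p = 8.06e-07). SMAC_04545 fell from 16.6 ± 20.5 to 0.194 ± 0.167 CPM (log2 fold change -6.28, SE 1.36, edgeR adjusted p = 0.00477), with replicates in mycelium that spread as widely as their mean; without wild-type mycelium replicate 2 its log2 fold change was -3.41 and its adjusted p 0.0523. SMAC_03952 itself did not pass the threshold between the tissues (log2 fold change -0.44, edgeR adjusted p = 0.15). Changes of at least 16-fold were seen for 16 genes that rose and 47 that fell. The tissues also differed in culture form and harvest, which the comparison cannot separate. The number of genes called was 1704 (754 higher, 950 lower) without wild-type mycelium replicate 1, 1396 (541 higher, 855 lower) without mycelium replicate 2 and 1696 without perithecia replicate 1. Lower genes were also the larger part with only the libraries compared (1270 higher, 1431 lower), with RLE factors (1322 and 1344) and in thinned libraries (1202 and 1290), so which direction held more genes depended on the setting.

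The same tissue comparison in the deletion strains gave 2489 genes in Δasm2 (1226 higher in perithecia, 1263 lower) and 3396 in ΔSMAC_03952 (1556 higher, 1840 lower). In ΔSMAC_03952 the fold changes correlated with gene length (Spearman 0.31); with length trends removed 3100 genes were called (1334 higher, 1766 lower), 2578 of them among the 3396. The sets followed below are those without this correction, and they were not followed again with it. Wild-type, Δasm2 and ΔSMAC_03952 libraries are independent of each other here, so each strain's set could be followed in the others. Of the 1401 genes that were higher in wild-type perithecia, 607 were also higher in Δasm2 perithecia and 38 were lower, with a median log2 fold change of 0.81 in Δasm2 against 1.30 in the wild type. In ΔSMAC_03952, 421 of them were higher and 135 lower, with a median of 0.46. Both sets of changes passed a gene set test (camera, adjusted p = 1.16e-25 for Δasm2 and 1.77e-07 for ΔSMAC_03952 with the preset correlation of 0.01; adjusted p = 0.00136 and 0.0368 with an estimated correlation, over 22 tests). The 1261 genes lower in wild-type perithecia gave 664 lower and 3 higher genes in Δasm2, and 645 lower and 44 higher in ΔSMAC_03952 (camera, adjusted p = 0.00136 and 0.00819 with an estimated correlation).

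A set chosen for its size in 1 strain is smaller on average in any other, so the reverse direction was set beside it. The 1226 genes higher in Δasm2 perithecia had a median of 1.40 in Δasm2 and 0.88 in the wild type, where 607 were higher and 3 lower. The 1556 genes higher in ΔSMAC_03952 perithecia had a median of 1.29 in their own strain, 0.45 in the wild type, where 421 (27.1%) were higher, and 0.85 in Δasm2, where 729 (46.9%) were higher. Whether these shares differ between strain pairs was not tested. Counted on library totals with no scaling factors, the split turned to 1438 higher and 1028 lower genes in Δasm2 and to 1953 higher and 1326 lower in ΔSMAC_03952, and the median log2 fold change of all tested genes was 0.20 and 0.24. The Δasm2 count was 1279 without its mycelium replicate 1, 1359 (690 higher, 669 lower) without its perithecia replicate 1 and 1182 without its perithecia replicate 2; the ΔSMAC_03952 count was 1806 and 1329 without its perithecia replicates 1 and 2.

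**Figure D3:**
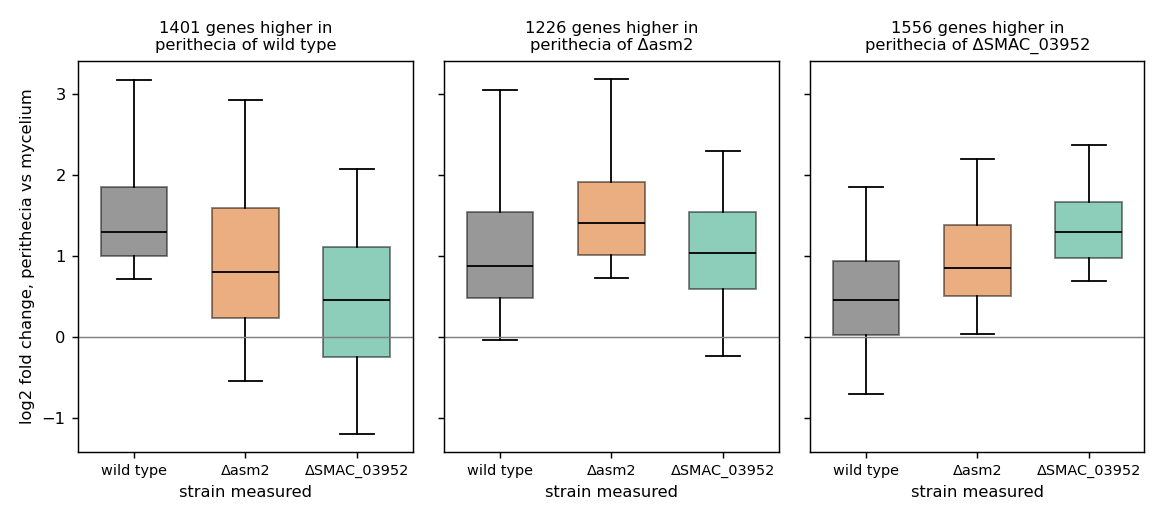
Each panel takes the genes called higher in perithecia of 1 strain (1401, 1226 and 1556 genes) and shows their log2 fold change between perithecia and mycelium (y axis) in the wild type, Δasm2 and ΔSMAC_03952 (x axis); boxes span the quartiles with the median as a line, and whiskers the 5th to the 95th percentile. Each set is largest in the strain that defined it; the wild-type set has medians of 1.30, 0.81 and 0.46, and the ΔSMAC_03952 set medians of 0.45, 0.85 and 1.29.

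In mycelium, Δasm2 differed from the wild type in 576 genes, 328 higher and 248 lower. SMAC_01390 rose from 0.492 ± 0.105 to 20.7 ± 1.76 CPM, a 41-fold change (log2 fold change 5.36, SE 0.42, edgeR adjusted p = 7.18e-05). SMAC_04544 rose from 38.6 ± 49.3 to 1371 ± 880 CPM (log2 fold change 5.15, SE 1.28, edgeR adjusted p = 0.0356), with wide spread in both groups. SMAC_02514 fell from 436 ± 11.8 to 3.32 ± 4.70 CPM (log2 fold change -6.91, SE 0.94, edgeR adjusted p = 0.00135); the replicates held 103 and 0 counts, and without the first the estimate, -15.60, rests on 0 counts. SMAC_08033 fell from 136 ± 44.1 to 1.98 ± 0.615 CPM (log2 fold change -6.13, SE 0.74, edgeR adjusted p = 7.12e-04). The count was 111 and 333 without wild-type replicates 1 and 2, 155 without Δasm2 replicate 1, 375 with only the libraries compared and 924 by DESeq2. SMAC_04544 had an adjusted p of 0.182 without wild-type replicate 1, 0.185 without Δasm2 replicate 1 and 0.0609 in a fit of only the libraries compared. Its log2 fold change was 4.24 and 4.26 in the first 2 of these fits and 8.47 without wild-type replicate 2.

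ΔSMAC_03952 mycelium differed from wild-type mycelium in 1023 genes, 392 higher and 631 lower. The fold changes correlated with gene length (Spearman -0.35, the strongest of the 11 comparisons), and the cause of this trend was not tested; with length trends removed 1097 genes were called, 816 of them among the 1023. SMAC_07759 fell from 98.7 ± 6.82 to 0.571 ± 0.260 CPM, 156-fold (log2 fold change -7.29, SE 0.96, edgeR adjusted p = 0.0019). SMAC_08033, lower also in Δasm2 mycelium, fell 102-fold to 1.23 ± 0.643 CPM (log2 fold change -6.67, SE 0.77, edgeR adjusted p = 0.00114). SMAC_09685 rose from 0.480 ± 0.236 to 89.9 ± 104 CPM (log2 fold change 7.48, SE 1.60, edgeR adjusted p = 0.0188). SMAC_09686 rose from 0.657 ± 0.472 to 82.8 ± 81.6 CPM (SE 1.59 on the log2 scale, edgeR adjusted p = 0.0228). The count was 92 and 479 without wild-type replicates 1 and 2, 548 and 668 without ΔSMAC_03952 replicates 1 and 2, 242 with only the libraries compared and 1920 by DESeq2. The calls of SMAC_09685 and SMAC_09686 ended without either wild-type replicate or without ΔSMAC_03952 replicate 1, with adjusted p from 0.0542 to 0.213; without the latter their log2 fold changes were 5.06 and 5.31.

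Δspt3 mycelium differed from wild-type mycelium in 5632 genes, 59.3% of those tested, 2761 of them higher and 2871 lower. Large decreases outnumbered large increases: 671 genes were lower by at least 16-fold and 112 higher. SMAC_12709, at 342 ± 6.30 CPM in the wild type, and SMAC_07760, at 176 ± 0.974 CPM, had 0 counts in both Δspt3 libraries. Against a floor of 3 counts over the group they were at least 3025-fold and at least 1557-fold lower (edgeR adjusted p = 8.98e-08 and 2.71e-07). SMAC_00556 rose from 2.59 ± 1.31 to 2581 ± 288 CPM, 981-fold (log2 fold change 9.94, SE 0.66, edgeR adjusted p = 1.72e-07). SMAC_08681 had 2 counts over the wild-type mycelium libraries and 1389 over the Δspt3 libraries (52.1 ± 43.0 CPM), a ratio of 1149 with an exact 95% interval of 317 to 9495 for counting error alone (edgeR adjusted p = 5.38e-06). Of 7379 genes at 10 CPM or more in wild-type mycelium, 38 had 0 counts in both Δspt3 libraries and 79 had at most 3 counts over both. Of these 79, 65 reached 1 CPM in each of the other 12 libraries. Of 395 genes under 1 CPM in wild-type mycelium, 20 reached 10 CPM in Δspt3, and the 20 passed the test. Perithecia of Δspt3 were not analysed here.

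Genes that were higher in the perithecia of the other deletion strains were mostly lower in Δspt3 mycelium. Of the 1226 genes higher in Δasm2 perithecia, 691 were lower in Δspt3 than in wild-type mycelium and 161 higher, with a median log2 fold change of -1.09. Of the 1556 genes higher in ΔSMAC_03952 perithecia, 835 were lower in Δspt3 and 132 higher, with a median of -0.87. These set tests passed with the preset correlation (camera, adjusted p = 6.6e-11 and 2.23e-11) and not with an estimated one (adjusted p = 0.083 and 0.39). Of all genes tested, 30.2% were lower and 29.1% higher in Δspt3. In counts of calls, the direction was not particular to Δspt3. Of the Δasm2 set, 215 genes (17.5%, against 6.64% of all genes) were lower and 27 higher in ΔSMAC_03952 than in wild-type mycelium. The ΔSMAC_03952 set gave 68 lower (4.37%, against 2.61%) and 15 higher genes in Δasm2 mycelium. These tests also passed only with the preset correlation (camera, adjusted p = 5.2e-10 and 3.98e-08). Tissue fold changes rose with gene length in Δasm2 and ΔSMAC_03952 (Spearman 0.11 and 0.31). Those of ΔSMAC_03952 and Δasm2 against wild-type mycelium fell with it (-0.35 and -0.12). Whether these trends gave the direction was not tested. The wild-type perithecium set shares its mycelium libraries with the Δspt3 comparison and gave 512 lower and 426 higher genes. The genes lower in wild-type perithecia gave 632 lower and 267 higher genes, with a median of -0.70. Chance values in the shared libraries pull both sets, and the difference between them was not tested.

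In perithecia, Δasm2 differed from the wild type in 1118 genes, 479 higher and 639 lower. SMAC_06022 rose from 10.7 ± 3.89 to 171 ± 1.15 CPM, 16-fold (SE 0.36 on the log2 scale, edgeR adjusted p = 4.11e-05), and SMAC_05843 from 1.47 ± 0.132 to 18.9 ± 1.35 CPM, 12.8-fold (log2 fold change 3.68, SE 0.36, edgeR adjusted p = 7.13e-05). SMAC_02514 fell from 410 ± 33.2 to 0.612 ± 0.167 CPM, 672-fold (log2 fold change -9.39, SE 1.09, edgeR adjusted p = 1.87e-04). SMAC_09351 fell from 612 ± 181 to 13.0 ± 11.8 CPM, 47.5-fold (log2 fold change -5.57, SE 0.70, edgeR adjusted p = 2.86e-04). The count was 625 and 704 without wild-type replicates 1 and 2 and 440 and 371 without Δasm2 replicates 1 and 2.

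ΔSMAC_03952 perithecia differed from wild-type perithecia in 1653 genes, 593 higher and 1060 lower, and 103 of the lower genes changed by at least 16-fold. SMAC_06842 fell from 121 ± 7.57 CPM to 0 counts in both libraries, at least 683-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 1.2e-06). SMAC_07669 fell from 1222 ± 108 to 0.614 ± 0.255 CPM (log2 fold change -10.88, SE 0.59, edgeR adjusted p = 4.7e-07). SMAC_08753 rose from 0.555 ± 0.0788 to 15.4 ± 3.37 CPM, 27.6-fold (log2 fold change 4.79, SE 0.88, edgeR adjusted p = 0.00349), and SMAC_08963 from 1.07 ± 0.431 to 24.8 ± 7.41 CPM, 22.8-fold (log2 fold change 4.51, SE 0.56, edgeR adjusted p = 2.34e-04). The count was 906 without wild-type replicate 1 and 766 and 618 without ΔSMAC_03952 replicates 1 and 2.

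Genes of the wild-type perithecium set made up most of the decreases in mutant perithecia. Of the 1401 genes higher in wild-type perithecia than in mycelium, 466 were lower in Δasm2 than in wild-type perithecia and 25 higher; for ΔSMAC_03952 the numbers were 658 and 22. Because these comparisons share the wild-type perithecia, 20 simulations with unchanged mutant groups were run. Their lists of mutant effects are nearly empty by construction, so the 0 genes they placed in both lists are chance with no effect and no reference for these overlaps; independent lists of these sizes would share 94.2 and 156 genes. The covariance of the log2 fold changes was -0.51 for Δasm2, against -0.08 in the simulations, and -0.72 for ΔSMAC_03952, against -0.07. SMAC_08033 is one example, at 1388 ± 71.0 CPM in wild-type perithecia, 47.1 ± 45.2 in Δasm2 and 1.73 ± 0.205 in ΔSMAC_03952 perithecia. The controls were not split, since each comparison would keep 1 wild-type library per tissue, so part of the excess may come from the shared controls. Sets from other libraries gave no common direction. Of the 1226 genes higher in Δasm2 perithecia, 239 (19.5%, against 11.2% of all) were lower in ΔSMAC_03952 than in wild-type perithecia and 65 higher. Of the 1556 genes higher in ΔSMAC_03952 perithecia, 63 (4.05%, against 6.73%) were lower in Δasm2 and 107 higher. These tests passed only with the preset correlation (camera, adjusted p = 0.0015 and 0.00541, against 0.39 and 0.629 with an estimated correlation).

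The effects of both deletions in perithecia ran in the same direction. There were 545 genes lower in both strains and 172 higher in both, against 71.3 and 29.9 for independent lists, and 7 with opposite calls. Simulations with unchanged groups, where few genes can be called at all, gave at most 1 gene called in the same direction, which is chance with no effect. The genes lower in both had a median of 80.8 CPM in wild-type perithecia, 24.1 in Δasm2 and 17.4 in ΔSMAC_03952 perithecia, and 432 of them (79.3%) belonged to the wild-type perithecium set. Pearson's correlation of log2 fold changes across genes was 0.73, against 0.48 in the simulations, and the covariance 0.69 against 0.08, a difference of 0.62. In mycelium, 149 genes were lower and 71 higher in both strains, against 16.5 and 13.5 for independent lists, and 5 had opposite calls; the covariance was 0.42, against 0.07 simulated. Δspt3 shared 462 lower and 240 higher genes with ΔSMAC_03952 mycelium (190.7 and 114 for independent lists) and 181 and 141 with Δasm2 mycelium (75 and 95.3), with 109 and 135 opposite calls. Across genes the correlations with Δspt3 were 0.32 for both strains, below the simulated 0.47 and 0.48, while the covariances were 0.65 for ΔSMAC_03952 and 0.59 for Δasm2, against 0.07 simulated for each. Genes are not independent replicates, and part of each excess may come from the shared wild-type libraries.

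Compared directly, Δasm2 perithecia differed from ΔSMAC_03952 perithecia in 427 genes, 369 of which (86.4%) were higher in Δasm2. The wild-type perithecium set, which comes from other libraries, was higher in Δasm2: 137 of the 1401 genes were called higher and 6 lower, with a median log2 fold change of 0.24 (camera, adjusted p = 9.09e-08 with the preset correlation, adjusted p = 0.0368 with an estimated correlation). The genes lower in wild-type perithecia had a median of -0.03 in this comparison, with 65 called higher and 24 lower (camera, adjusted p = 0.143). As shares, 5.15% were higher and 1.90% lower, against 3.88% and 0.611% of all genes tested, so some members moved in each direction. The count was 153 and 193 without Δasm2 replicates 1 and 2, 106 and 90 without ΔSMAC_03952 replicates 1 and 2, 1867 with only the libraries compared and 689 by DESeq2.

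**Figure D4:**
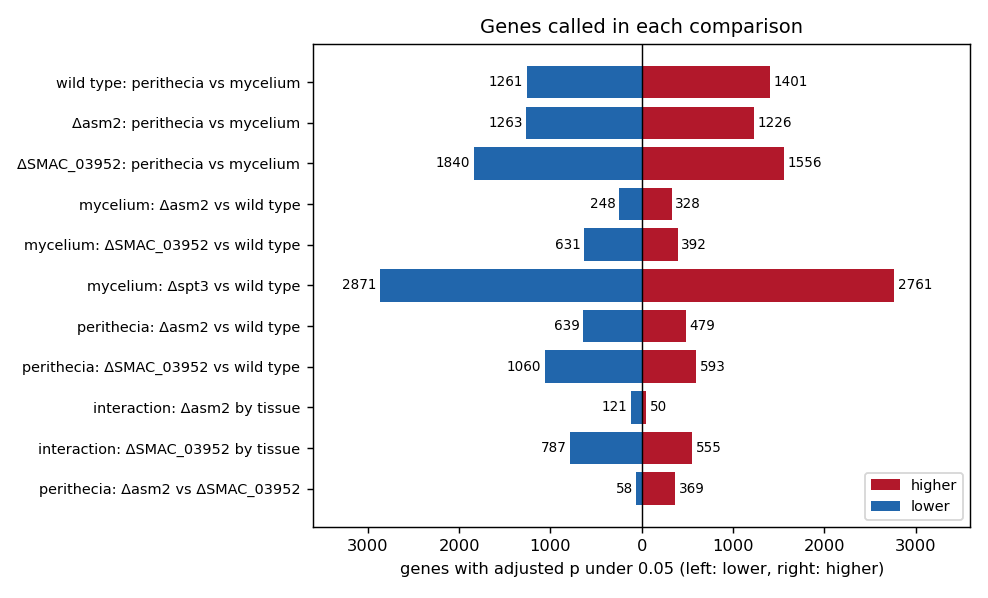
Bars give the number of genes with an adjusted p under 0.05 in each of the 11 comparisons, to the right for higher and to the left for lower (x axis, number of genes; rows, comparisons). Δspt3 against the wild type has the longest bars, 2761 and 2871 genes, and the Δasm2 interaction has the fewest genes in all, 50 and 121.

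Whether a deletion acted differently in perithecia than in mycelium was tested as an interaction. In Δasm2, 171 genes passed, 50 with a higher and 121 with a lower effect in perithecia. SMAC_01548 stood at 800 ± 188 CPM in wild-type and 341 ± 21.9 in Δasm2 mycelium, and at 21.4 ± 11.3 and 115 ± 50.8 CPM in the perithecia (interaction 3.66 on the log2 scale, SE 0.57, edgeR adjusted p = 0.0101). SMAC_08453 had an interaction of 3.47 (SE 0.77, edgeR adjusted p = 0.046). SMAC_04106 was at 1.42 ± 0.866 CPM in wild-type and 41.8 ± 37.6 in Δasm2 mycelium, and at 4.80 ± 3.25 and 1.83 ± 1.03 CPM in perithecia (interaction -6.30, SE 1.08, edgeR adjusted p = 0.0159). SMAC_08989 had an interaction of -5.29 (SE 1.12, edgeR adjusted p = 0.0367). Without Δasm2 mycelium replicate 1 the interactions of SMAC_04106 and SMAC_08989 were -4.77 and -4.11. They were larger in other fits, -6.98 for SMAC_04106 without Δasm2 perithecia replicate 1 and -5.74 for SMAC_08989 without Δasm2 perithecia replicate 2. Each left-out library moved the count by over 1.5 times: 7 and 93 genes passed without wild-type mycelium replicates 1 and 2, 50 and 96 without wild-type perithecia replicates 1 and 2, 28 and 344 (183 higher, 161 lower) without Δasm2 mycelium replicates 1 and 2, and 15 and 19 without Δasm2 perithecia replicates 1 and 2. Each of these 4 genes lost its call in at least 3 of these 8 fits, and the count was 673 by DESeq2, 423 with only the libraries compared and 306 with length trends removed.

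In ΔSMAC_03952, 1342 genes passed the interaction test, 555 higher and 787 lower. SMAC_01759 stood at 77.2 ± 28.8 CPM in wild-type and 12.1 ± 8.60 in ΔSMAC_03952 mycelium, and at 9.67 ± 3.09 and 89.7 ± 17.8 CPM in perithecia (interaction 5.84, SE 0.98, edgeR adjusted p = 0.00429). SMAC_02873 had an interaction of 5.86 (SE 1.32, edgeR adjusted p = 0.0153). SMAC_09685 (interaction -9.73, SE 2.26, edgeR adjusted p = 0.0199) and SMAC_09686 (-12.45, SE 2.49, edgeR adjusted p = 0.011) were the genes that rose in ΔSMAC_03952 mycelium. Without ΔSMAC_03952 perithecia replicate 2 the SMAC_09686 estimate, -16.82, rests on 0 counts in that group. Both genes were also high in Δasm2 mycelium replicate 1, at 37.1 and 43.9 CPM, against 0.330 CPM each in replicate 2. In perithecia they stood at 2.84 ± 0.306 and 8.02 ± 1.72 CPM in the wild type and at 0.587 ± 0.0125 and 0.149 ± 0.211 CPM in ΔSMAC_03952, which rest on 10 and 3 counts; neither difference in perithecia passed the threshold (edgeR adjusted p = 0.425 and 0.0946). Of the genes with an interaction in Δasm2, 38 of the 50 higher and 104 of the 121 lower had one of the same direction in ΔSMAC_03952, against 2.92 and 10.0 for independent lists of these sizes; simulations with unchanged groups call almost no interaction and shared 0 by construction. The covariance of the 2 interactions was 0.82, against 0.15 in the simulations, and part of the excess may come from the shared wild-type libraries. The count was 283 without wild-type mycelium replicate 1, 385 without wild-type perithecia replicate 1, 454 and 266 without ΔSMAC_03952 perithecia replicates 1 and 2, and 2080 by DESeq2. Higher genes were the larger part with only the libraries compared (785 higher, 772 lower), without wild-type mycelium replicate 2 (481 and 477) and without ΔSMAC_03952 mycelium replicate 2 (630 and 534). Without wild-type mycelium replicate 1 the calls of SMAC_02873, SMAC_09685 and SMAC_09686 ended (edgeR adjusted p from 0.0584 to 0.0837), as they did without ΔSMAC_03952 perithecia replicate 2. SMAC_09685 lost its call in 5 of the 8 fits with a library left out, SMAC_02873 also without wild-type perithecia replicate 1 and SMAC_09686 also without ΔSMAC_03952 perithecia replicate 1.

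The authors' deposited table lists 2960 genes with an adjusted p under 0.05 for wild-type perithecia against mycelium, 894 for Δasm2, 1803 for ΔSMAC_03952 and 5682 for Δspt3 against wild-type mycelium, and 1562 and 1991 for Δasm2 and ΔSMAC_03952 against wild-type perithecia. Between 97.5% and 99.7% of the genes called here in these 6 comparisons are called in the authors' deposited table, with the same sign. In the other direction, 2640 of the 2960, 571 of the 894, 1020 of the 1803 and 5489 of the 5682 were called here. In perithecia, 1107 of the 1562 and 1638 of the 1991 were. Both analyses start from the same counts, so the shared calls are no independent check.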

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

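The fits with length offsets, the fits on thinned libraries, the exchange of replicate numbers and the direct test between the interactions were added after the interaction counts were seen. No group has enough libraries for a search for single libraries that stand apart.

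The effect of the Δasm2 deletion differed between perithecia and mycelium in 171 genes, and that of the ΔSMAC_03952 deletion in 1342 genes, by the interaction test. Single genes with such a difference were SMAC_01548 (3.66 on the log2 scale), SMAC_08453 (3.47), SMAC_04106 (-6.30) and SMAC_08989 (-5.29) in Δasm2, and SMAC_02873 (5.86), SMAC_01759 (5.84), SMAC_09686 (-12.45) and SMAC_09685 (-9.73) in ΔSMAC_03952. SMAC_04106, SMAC_09685 and SMAC_09686 had high counts in mutant mycelium with replicates that spread about as widely as their mean. Their standard errors of 1.08, 2.26 and 2.49 rest on a spread estimated over all 7 groups. They need not cover the spread within mutant mycelium.

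The ΔSMAC_03952 count is 7.85 times the Δasm2 count, a ratio that depends on the setting: 3.09 by DESeq2, 3.68 in fits of only the libraries compared, 3.78 with replicate numbers exchanged and 40.4 (283 against 7 genes) without wild-type mycelium replicate 1. With each library's trend with gene length removed, the numbers were 1375 and 306, a ratio of 4.49, so a length trend as the whole cause is argued against, although the fold changes of the ΔSMAC_03952 interaction correlated with gene length across genes before the offsets (Spearman 0.33, against 0.16 for Δasm2). With all libraries thinned to the smallest total the numbers were 1219 and 153, a ratio of 7.97, which argues against unequal depth. Tested directly, the 2 interactions differed in 14 of 9499 genes, in 15 with length trends removed and in 9 in thinned libraries. In the main fit 871 of the 9499 had an unadjusted p under 0.05, where chance alone would give a share of about 0.05. Across genes the difference correlated with gene length (Spearman 0.37). Of the Δasm2 genes, 38 of the 50 higher and 104 of the 121 lower were shared with ΔSMAC_03952 in direction. A stronger tissue-dependent effect of the ΔSMAC_03952 deletion across many genes is a hypothesis that stays open, and so is a common effect that passes the threshold more often in 1 strain.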

How the results depend on the processing

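Library totals, thinning, length offsets and the exchange of replicate numbers were picked only after the results were seen. Of 35 named results past the threshold none changed direction under any alternative. Apart from SMAC_03952, these genes were picked for large fold changes, in comparisons of 2 groups with replicates that did not overlap. A change of direction was therefore hardly possible, and its absence says little about other called genes. Of the 516 alternative values of named results, 472 kept their side of the threshold and 44 lost it, 41 of them with a library left out; SMAC_04544 in Δasm2 mycelium (only the libraries compared, replicate block) and the SMAC_08453 interaction (library totals) made up the other 3. RLE factors, no filter, the minimum fold change, library totals and thinning changed no count of calls by over 1.5 times; the cause of the following changes was not tested. With DESeq2, counts were 924 (main 576) for Δasm2 and 1920 (1023) for ΔSMAC_03952 against the wild type in mycelium, 673 (171) and 2080 (1342) for the interactions and 689 (427) for Δasm2 against ΔSMAC_03952 in perithecia. Its lists for mycelium shared 424 genes between Δasm2 and ΔSMAC_03952 (main 220), 518 between Δasm2 and Δspt3 (322) and 1221 between ΔSMAC_03952 and Δspt3 (702). In fits of only the libraries compared, counts were 375, 242, 423 (Δasm2 interaction) and 1867 (Δasm2 against ΔSMAC_03952), where 37 of the 242 ΔSMAC_03952 genes were higher. With length offsets, added later, the Δasm2 interaction gave 306. Library totals without scaling factors, also added later, moved the median log2 fold change of all genes to 0.20 for tissue in Δasm2, 0.24 for tissue in ΔSMAC_03952, -0.19 for Δspt3 and 0.11 for the ΔSMAC_03952 interaction; other changes are relative to it.

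With 1 library left out, the lone library being assumed to vary like the other groups, counts ranged from 1396 (without wild-type mycelium replicate 2) to 1907 for tissue in the wild type, from 1182 (Δasm2 perithecia 2) to 2047 in Δasm2 and from 1329 (ΔSMAC_03952 perithecia 2) to 2892 in ΔSMAC_03952. In mycelium they ranged from 111 to 686 for Δasm2, from 92 to 668 for ΔSMAC_03952 and from 4355 to 5503 for Δspt3, each lowest without wild-type mycelium replicate 1. In perithecia the ranges were 371 to 704 for Δasm2, 618 to 1175 for ΔSMAC_03952 and 90 to 193 between them, lowest without mutant replicate 2. For the interactions they were 7 (wild-type mycelium 1) to 344 (Δasm2 mycelium 2) and 266 (ΔSMAC_03952 perithecia 2) to 1343. Fewer libraries leave fewer degrees of freedom by construction.

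Replicate numbers did not pair the libraries alike: over 21 pairs of groups the deviations of same-numbered libraries correlated between -0.33 and 0.38, 11 above 0.1 and 6 below -0.1. Wild-type mycelium correlated negatively with each of the 6 other groups and held 5 of the 6 values below -0.1, while the 11 above 0.1 were among the 15 pairs of other groups. The replicate block raised the count in all 11 comparisons, from 171 to 231 for the Δasm2 interaction and from 1023 to 1360 for ΔSMAC_03952 mycelium, and by under 1.5 times in each. With the numbers of the wild-type mycelium libraries exchanged for that reason, an alternative chosen after seeing the data, counts were 916, 2080, 556 and 2101 for Δasm2 and ΔSMAC_03952 mycelium and the 2 interactions. The planned lists for pathways and cell type markers were not run, with any alternative, for lack of names.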

Other observations

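The tests in this part on SMAC_03952 reads, on SMAC_02514 and on genes 3 places apart were chosen after the results were seen. The analysis of neighbouring genes was itself added after the data were seen, and for its test on genes 2 places apart only the bounds were written before that test was run.

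Genes that changed together lay next to each other more often than chance gives. In each of the 11 comparisons, neighbouring genes were called in the same direction more often than with calls shuffled over positions, by 1.26 times (tissue in ΔSMAC_03952) to 3.70 times (Δasm2 interaction, 6 pairs). In Δspt3 mycelium there were 1915 such pairs against a shuffled mean of 1493 (permutation p = 0.001, the smallest that 1000 shuffles can give). Runs of 4 or more neighbours with the same direction numbered 164, against a shuffled mean of 82.8 and a maximum of 106. The longest, picked after its values were seen, held 12 genes lower in Δspt3, with log2 fold changes from -9.87 to -0.71 and a median of -4.39. Wild-type perithecia against mycelium gave 21 runs against a shuffled mean of 4.97 and a maximum of 13, and the longest there held 7 genes, higher in perithecia by a median of 1.79. The same 7 genes formed the longest run of higher genes in Δasm2 (median 1.91) and in ΔSMAC_03952 (median 1.43).

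Reads counted for 2 overlapping or adjacent gene models may produce such pairs. At 3 places apart an excess was present for Δspt3, 1600 pairs against 1528 at the upper end of the shuffled range, and for wild-type perithecia against mycelium, 393 pairs against 363, which argues against shared reads as the whole cause in both. For ΔSMAC_03952 against wild-type perithecia the number at 3 places, 161, lay barely above the upper end, 160, and at 2 places, 146, within the range. Of the 9 comparisons with at least 500 calls, pairs 2 places apart exceeded the shuffled range in 5. Outside Δspt3 and wild-type tissue, shared reads cannot be told apart from other sources, since the counting rules for overlapping models are not given in the sources used here. In those 2 comparisons the excess at 3 places was 1.09 and 1.19 times the shuffled mean. The shuffles moved calls over genes whatever their expression or length. An excess over them therefore does not show coordinated expression of neighbouring genes. That the Δspt3 deletion alters transcription of chromosomal neighbourhoods is a hypothesis; no biological explanation was tested.

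SMAC_03952 kept 9.73% of its wild-type level in mycelium and 23.0% in perithecia of its own deletion strain. Wild-type material mixed into the deletion libraries would bring every abundant wild-type transcript at that share. In perithecia, 22 genes with at least 100 CPM in both wild-type libraries lay below 1/10 of it in both deletion libraries. In mycelium no gene did. At a bound of 3/4 of the share, set for mycelium after that result, 5 of 1909 such genes lay below, at 6.34% or less. A mixture as the whole source is therefore argued against in perithecia. In mycelium the bound was loosened after the first gave no gene, so the number of genes below it does not decide the question there. SMAC_07759 and SMAC_08033, named above for their falls in ΔSMAC_03952 mycelium, stood 156-fold and 102-fold below wild-type mycelium, at 0.571 and 1.23 CPM. A mixture with 9.73% of such wild-type mycelium would not leave them so low. These 2 genes, picked for their falls, argue against a mixture as the whole source in mycelium. Reads from a part of the gene model outside the deleted segment are a candidate source that cannot be told apart from others, because coverage along the gene was not used here.

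SMAC_02514 stood at 0 to 6.64 CPM in the 4 Δasm2 libraries and between 99.3 and 444 CPM in the other 10. Of 13 genes lower by over 4 on the log2 scale than the wild type in both Δasm2 tissues, it was the only 1 not called lower in ΔSMAC_03952 or Δspt3 (edgeR adjusted p = 0.389 and 0.977 for ΔSMAC_03952 mycelium and perithecia and 0.0708 for Δspt3). The rule restates why SMAC_02514 was picked, so that it met the rule was given in advance. The count of 1 shows only that no other gene did. That SMAC_02514 is the locus deleted in Δasm2 is a hypothesis. It stays undecided because no source used here pairs the identifier with that name. The 103 counts in Δasm2 mycelium replicate 1 are not explained.

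SMAC_12697, picked after its values were seen as the most abundant gene model of wild-type mycelium, stood at 48512 and 20698 CPM there, at 6418 to 7916 CPM in Δasm2 mycelium and ΔSMAC_03952 mycelium replicate 2, at 4653 CPM in ΔSMAC_03952 mycelium replicate 1 and at 38.3 and 48.7 CPM in Δspt3.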
